A study of Mus musculus with 6 samples.

How the data were processed

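Tumours were grown by injecting MC38 cells, a mouse colon adenocarcinoma line, under the skin of C57BL/6J mice aged 6 weeks. Per the labels, treated mice received GW4064, a synthetic agonist of the farnesoid X receptor, 2 times per week from day 6, and control mice did not. Each of the 6 libraries (3 control, 3 GW4064) holds the cells of dissociated tumour, made with the Chromium Single Cell 3' v3 kit. The series title names glycocholic acid, checkpoint therapy, FBXW7 and CD73 (gene Nt5e). The labels do not state whether libraries with the same number share a day, a cage or a mouse, nor that each library comes from a separate mouse.

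The deposited matrices hold raw UMI counts per gene and cell barcode, not normalized, for barcodes already called as cells. Per the file headers they were made by the authors with Cell Ranger 5.0.0. Per the labels, Cell Ranger and STAR with genome build mm10 were used, with no versions. The 32285 genes of the files were matched by Ensembl gene ID to GENCODE vM21 (GRCm38), which held 32235 of them (99.85%), and positions are from there. The libraries held 51532 barcodes and 738315619 UMIs. Per library this was 93575944, 110536024 and 122780277 UMIs in control tumours and 113250181, 167998915 and 130174278 under GW4064. Intervals and limits for a count of 0 (3 counts) cover counting error only.

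Barcodes with fewer than 500 UMIs, fewer than 300 genes or more than 20% mitochondrially encoded UMIs were removed (644 barcodes). Scrublet scores were computed per library, and the highest 6% of scores in each library were removed as doublets (3057 barcodes). This rule was set after the automatic Scrublet threshold had marked 0.01 to 0.047% of cells. The 47831 retained cells and the doublets had been clustered together with scanpy 1.11.5 and leidenalg 0.10.2. Counts were scaled to 10000 per cell, logged and reduced to 30 principal components of the 2000 most variable genes, with 15 neighbours, Leiden resolution 1 and no integration across libraries. This gave 20 clusters. The T and NK cells were clustered again into 8 sub-clusters.

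Clusters were named from 24 marker lists written before the data were examined. A marker counted as held at 40% or more of the highest cluster and in at least 5% of the cluster's cells. A name needed at least 3 held markers, and among the 10 genes of highest fold no other type could have more markers. A cluster with a low median UMI count for its libraries and no own marker among these 10 genes also stayed unnamed. Clusters with 4 Y-linked transcripts summed below 10% of the highest cluster could only be named tumour, and others could not. The exact form of this rule, and the reference used for the T-cell subsets, were set after clusters and their sizes per library had been seen, but before any test between groups. Unnamed clusters stayed in the sums over whole tumours and in the denominators of shares, and in no class. Names end in -like because no sorted reference was used.

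UMI counts were summed over the cells of a class in each library. These sums held 67358949 to 140408058 UMIs in tumour-like cells, 925362 to 2651976 in monocyte/macrophage-like cells, 880327 to 2090080 in fibroblast-like cells and 99347 to 677684 in T-cell-like cells. Groups were compared with the edgeR 4.0.16 quasi-likelihood F test (TMM scaling, filterByExpr by group, no covariate), adjusted by Benjamini-Hochberg over all genes tested, with 0.05 as the threshold. Other classes were tested only with at least 30 cells in every library, which only fibroblast-like cells met. An added test in CD8 T-like cells broke this rule, with 12 to 29 cells in the control libraries. Fold changes are GW4064 over control on the log2 scale with SE. Levels are CPM (UMIs scaled to the effective library size) with SD over 3 libraries. Shares of cells were tested with the same edgeR test on cell numbers, with a two-sided exact permutation test beside it.

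For the gene lists, 26 lists written before the data were examined were tested with camera in limma 3.58.1 at a preset correlation of 0.01, over lists with at least 5 tested members. The correlation estimated from the data and fry were run beside it. Members of a list can move together, so counts of members past the threshold over the list alone are not separate results. Named genes followed a rule fixed before the data were examined. It named 6 genes in every class (Nt5e, Fbxw7, Nr1h4, Nr0b2, Cd274, Pdcd1). It also named the largest changes past the threshold with no overlap between groups, a mean of at least 20 CPM in a group and at least 0.2 of the level of the highest class. In a main class with fewer than 3 genes past the threshold it named the 5 of lowest p, and in each list described the 2 to 4 members of lowest p. Genes outside this rule are marked as chosen after their values were seen. A single gene among those named by this rule is left out of the text.

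Alternatives changed 1 choice at a time: DESeq2 1.42.0, DESeq2 size factors in edgeR, no filter on low counts, a replicate block, Leiden resolutions 0.5 and 2, at least 1000 genes per cell, at most 10% mitochondrial UMIs, doublets kept, and each library left out. For shares, other denominators were also used. Every split of the 6 libraries into 3 and 3 was also tested. The tests were tried on simulated data made with the real means, sizes and dispersions and 200 changed genes. At 2-fold, edgeR recovered 58.2% of the changed genes in tumour-like cells (14494 genes tested), 49.3% in monocyte/macrophage-like cells (8107), 23.8% in T-cell-like cells (4167), 49.3% in fibroblast-like cells (8129) and 53.7% in whole tumours (15615). At 4-fold it recovered 92.2, 98.4, 92.4, 93.9 and 87.9%. False calls were 3.1, 6.8, 4.8, 8.4 and 6.9% of calls. The simulated genes were drawn independently and no simulated library stood apart. With correlated genes or a deviating library the share recovered can be lower, so 0 calls do not show that large changes are absent. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, igraph 0.11.9, matplotlib 3.10.9 and R 4.3.3 were used. NK-like, dendritic-like, endothelial-like and mast/basophil-like cells were too few for a gene test. The sequence reads were not analysed here.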

Results

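Single-cell transcriptomes of MC38 tumours were compared between 3 control libraries and 3 GW4064 libraries, to ask how activating the farnesoid X receptor changes the tumour's cells. The retained cells numbered 7270 to 8977 per library, with a median of 10147 to 16321 UMIs per cell. As the labels do not say that each library is a separate mouse, every p-value measures only the spread between these samples. GW4064 replicate 2 stood apart in its profile. Ribosomal protein genes took 29.4% of its UMIs against 22.2 to 24.1% in the other 5 libraries, and Malat1, a nuclear long non-coding RNA, reached 6206 CPM against 12428 to 16679. Its values are named below where they decide a result.

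GW4064 tumours held more macrophages and NK cells. Monocyte/macrophage-like cells were 2.35 ± 0.343% (SD, n = 3) of retained cells in control tumours and 4.34 ± 0.485% under GW4064 (log2 fold change 0.89 ± 0.23 SE, adjusted p 0.0286). NK-like cells, innate killer lymphocytes, were 0.127 ± 0.0781% and 0.488 ± 0.205% (1.94 ± 0.53, adjusted p 0.0286), counted as 3 to 14 cells per control library and 27 to 62 per GW4064 library. T-cell-like cells were 1.04 ± 0.730% and 2.34 ± 0.262% (adjusted p 0.102), and antigen-presenting dendritic-like cells 0.265 ± 0.0746% and 0.440 ± 0.0804% (adjusted p 0.102). In these 4 classes every GW4064 library lay above every control library. The exact permutation p was 0.1 for each, the smallest that 3 against 3 libraries allow, and 0.2 after adjustment over classes.

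**Figure D1:**
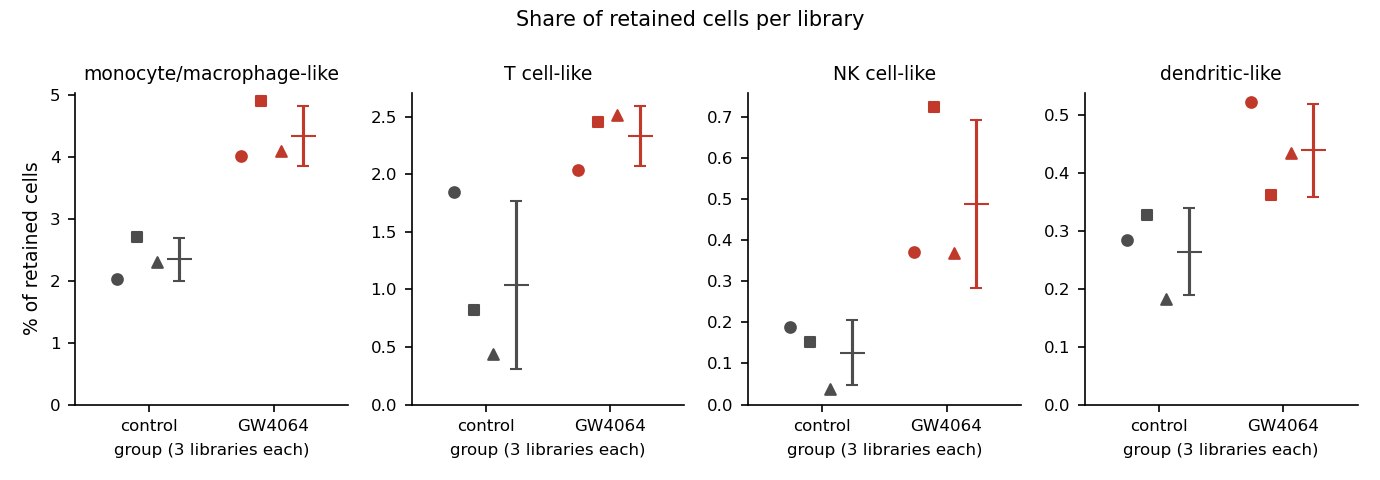
Share of retained cells per library in 4 immune classes (y axis, % of retained cells; x axis, group), with replicates 1, 2 and 3 as circle, square and triangle and the mean with SD beside them. The monocyte/macrophage-like shares lie between 2.03 and 2.71% in control and between 4.02 and 4.89% in GW4064 libraries.

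Both calls depend on single libraries and on processing choices. The macrophage call was lost without GW4064 1, 2 or 3 (adjusted p 0.0706, 0.132 and 0.0963) and without control 1 or 2 (0.0612 and 0.0689). The NK call was lost without GW4064 1, 2 or 3 (0.0706, 0.132 and 0.0840) and without control 2 (0.0689). Over all share alternatives the lowest adjusted p of any class ran from 0.000201 to 0.2. Among immune cells alone neither class passed, and the macrophage log2 fold change turned to -0.10 (adjusted p 0.760). NK-like cells did not pass with at least 1000 genes per cell (0.0825) or when clusters without Y-linked transcripts were added to the tumour-like cells (0.0681 and 0.0731). T-cell-like cells passed without control 1 (0.000201), where they were 1.85% of cells against 0.819 and 0.442% in controls 2 and 3, with at least 1000 genes per cell, and without the unnamed T sub-cluster. Fibroblast-like cells were 0.989 ± 0.312% and 1.49 ± 0.359% (adjusted p 0.180), endothelial-like cells 0.136 ± 0.0818% and 0.169 ± 0.0691% (0.523), and mast/basophil-like cells 0.00840 ± 0.0146% and 0.0276 ± 0.0171% (0.241). Tumour-like cells were 70.6 ± 7.63% and 81.6 ± 5.30% (0.396). Clusters left without a name held 24.5 ± 6.57% and 9.10 ± 5.98% of cells. The largest of them, high in collagen transcripts and without Y-linked transcripts, held 18.9 ± 6.05% and 5.63 ± 4.59%. Another without Y-linked transcripts, with few UMIs per cell, held 4.58 ± 0.795% and 2.85 ± 1.20%. The tumour-like share leaves both out, so its higher value does not show more cells without Y-linked transcripts under GW4064. With both counted in, the share of such cells was lower in each GW4064 library than in each control library. These shares of unnamed clusters had no test.

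Within the T and NK cells no subset passed the threshold in the test of shares. CD8 T-like cells, the cytotoxic subset, made up 28.7 ± 11.4% of T-cell-like and NK-like cells in control and 38.3 ± 15.02% in GW4064 tumours (adjusted p 0.559). CD4 T-like helper cells were 9.30 ± 2.43% and 11.3 ± 4.24% (0.795), and regulatory T-like cells, which restrain immune responses, 15.5 ± 7.86% and 14.0 ± 3.86% (0.964). NK-like cells were 10.99 ± 4.02% and 17.0 ± 5.21% (0.559), and an unnamed sub-cluster 35.6 ± 19.2% and 19.5 ± 9.27% (-0.94 ± 0.47, 0.305). With at least 1000 genes per cell the unnamed sub-cluster passed (adjusted p 0.0459). In the edgeR test 0 of 5 subsets passed, 0 had an unadjusted p under 0.05, and 0 passed the exact permutation test. Control replicate 3 contributed only 34 T-cell-like cells.

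In macrophages, interferon-induced genes were among those that rose under GW4064, and Lyve1 was among the 3 that fell. Ly6a (Sca-1), an interferon-induced surface protein, rose from 58.7 ± 13.6 to 402 ± 199 CPM (SD, n = 3; log2 fold change 2.79 ± 0.35 SE, adjusted p 0.00706), and its relative Ly6i from 1.97 ± 1.72 to 25.97 ± 8.08 CPM (3.77 ± 0.54, 0.00706). Lyve1, a hyaluronan receptor of tissue-resident macrophages, fell from 54.9 ± 12 to 12.8 ± 4.91 CPM (-2.08 ± 0.29, 0.00706). Cstdc4, a stefin-type protease inhibitor, fell from 26.2 ± 16.4 to 0.780 ± 0.427 CPM (-4.86 ± 0.64, 0.00706). Of 8313 genes tested with edgeR, 19 passed (16 up, 3 down).

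Other macrophage genes that rose by the naming rule were Ifitm1, which blocks virus entry (2.81), Slamf8, a myeloid surface receptor (2.34), Gbp2, an interferon-induced GTPase (2.32), and Fcgr4, an activating antibody receptor (1.92). The arginine-synthesis enzyme Ass1 (1.68) and the uridine phosphorylase Upp1 (1.49) rose as well. Their adjusted p values ran from 0.0141 to 0.0359. The checkpoint ligand gene Pdcd1lg2 (PD-L2) rose from 2.18 ± 1.15 to 19.2 ± 4.07 CPM (3.12 ± 0.45, 0.00706). Ly6a and Ly6i share sequence with each other and with other Ly6 genes, as Cstdc4 does with other stefins, so reads may have been divided between copies. Among the 19 genes, 6 were below 0.2 of the level in the highest class, where RNA from other cells weighs more.

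The macrophage calls depend on control replicates 1 and 3. Without control 1 or without control 3 edgeR called 0 genes (483 and 458 at unadjusted p under 0.05, lowest adjusted p 0.0571 and 0.0736). It called 199 genes without GW4064 1 and 12 without GW4064 2. Slamf8 also lost its call without GW4064 2 or 3 (0.0779 and 0.0534), as did Fcgr4, Ass1, Upp1 and Gbp2, and Ifitm1 without GW4064 2 (0.0779). At Leiden resolution 0.5 Ifitm1 had a log2 fold change of 1.33 and did not pass (0.0974), and with DESeq2 Gbp2 did not (0.120). Upp1 lost it without control 2 too (0.0908). DESeq2 called 47 genes, 18 of them shared. Over 15 alternatives the adjusted p of Ly6a ran from 8.86e-36 to 0.0736, and the log2 fold change from 2.19 to 3.15. That of Lyve1 ran from -2.31 to -1.83. The groups did not overlap in 980 of the tested genes (11.8%), where chance gives 10%.

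**Figure D2:**
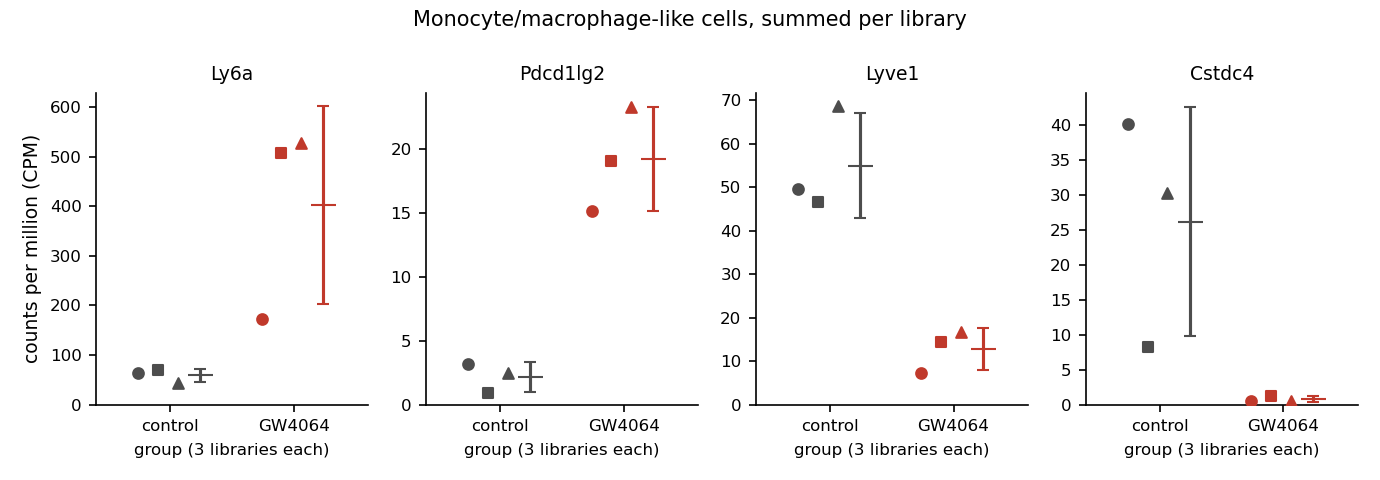
CPM of 4 genes in monocyte/macrophage-like cells (y axis, CPM; x axis, group), 1 point per library with replicates 1, 2 and 3 as circle, square and triangle, and the mean with SD beside them. Ly6a and Pdcd1lg2 are higher, and Lyve1 and Cstdc4 lower, in all 3 GW4064 libraries.

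Gene lists in macrophages pointed to interferon-gamma and antigen presentation. The list of interferon-gamma chemokines and regulators (14 members tested) had a median log2 fold change of 1.26 and an adjusted p of 7.60e-17, and with the estimated correlation an adjusted p of 0.406. Gbp4 (2.72 ± 0.41, 0.0115), an interferon-induced GTPase, and Gbp2 rose, and all 14 members passed when adjusted over the list alone. The MHC class I list, genes that present intracellular peptides, had a median of 0.79 (adjusted p 3.38e-16, estimated 0.406). Its leading members were Tapbp (0.89, 0.0534), H2-Q7 (1.28, 0.0808) and Psmb10 (0.96, 0.0902), and 16 of 17 passed when adjusted over the list alone. Lists of type I interferon response (1.78e-06, with Irf7 at 1.44 and Zbp1 at 1.44), MHC class II (0.000227, H2-Ab1 at 0.61 and H2-Aa at 0.59) and cell cycle (0.000278, Bub1 at 0.94 and Mcm2 at 0.68) were also shifted upward (estimated 0.406 for each). So were hypoxia and glycolysis (0.00668, Ndrg1 at 0.62 and Pfkp at 0.47) and checkpoint genes (0.0113, Pdcd1lg2 and Cd274), with estimated 0.450 and 0.406. Adjusted over the list alone, 6, 0, 0, 1 and 1 members of these 5 lists passed. Mitochondrially encoded genes (0.00190), cholesterol synthesis (0.00668) and extracellular matrix (0.0416) were shifted downward, with 0, 0 and 3 members past when adjusted over the list alone (estimated 0.450, 0.406 and 0.450). Their leading members were mt-Nd6 (-0.72) and mt-Nd5 (-0.40), Cyp51 (-0.56) and Sc5d (-0.82), and Col3a1 (-1.57) and Fn1 (-1.05). Col3a1 stood at 0.01 of its level in fibroblasts. With the estimated correlation 0 of 21 lists passed, and 0 passed fry (lowest adjusted p 0.191). Without control 3, 6 lists passed in place of 10. Cholesterol synthesis passed in 7 of 10 settings (0.746 with doublets kept) and extracellular matrix in 5 of 10 (0.577 without GW4064 1). Checkpoint genes passed in 7 (0.140 without GW4064 1), hypoxia in 8 (0.120 without control 1), mitochondrial genes in 8 (0.111 without GW4064 2) and cell cycle in 9 (0.0634 without control 2).

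In T cells, granzymes and the chemokine Ccl1 rose. Ccl1, a ligand of the receptor CCR8, went from 26.2 ± 34.5 to 232 ± 88.2 CPM (SD, n = 3; log2 fold change 3.74 ± 0.54 SE, adjusted p 0.00319). Granzymes are the proteases that killer cells release into targets. Gzmd rose from 13.0 ± 4.40 to 354 ± 346 CPM (4.79 ± 0.74, 0.00396), Gzma from 3.09 ± 3.00 to 65.4 ± 17.7 CPM (4.08 ± 0.65, 0.00449) and Gzme from 36.6 ± 33.6 to 316 ± 228 CPM (3.43 ± 0.65, 0.0342). These 4 were the only genes past the threshold among 4411 tested with edgeR.

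The 3 granzymes were named after their values were seen, since they stood at 0.057, 0.038 and 0.119 of their level in NK-like cells. Gzmd and Gzme are closely related neighbours, so reads may be shared between them. They are also among the leading genes of the T and NK sub-clusters, and Ccl1 leads a CD4 T-like sub-cluster, so clustering and test are not independent. DESeq2 called 0 genes, with 134 at unadjusted p under 0.05. The adjusted p of Gzma was 0.145 without control 1, and that of Gzme 0.145 without control 1 and 0.259 without GW4064 2. Over all alternatives they ran to 0.173 for Gzma, 0.999 for Gzme, 0.0632 for Gzmd and 0.632 for Ccl1. The log2 fold changes ran from 3.83 to 7.35 for Gzma, 2.48 to 4.80 for Gzme, 3.67 to 5.25 for Gzmd and 2.83 to 5.12 for Ccl1. In control libraries Gzma rested on 1, 1 and 0 UMIs. The edgeR count was 17 without GW4064 1, 7 without control 3 and 2 without control 1. With at least 1000 genes per cell 4 genes passed, 2 of them shared, and Ccl1 did not (0.487). No overlap was seen for 529 genes (12%, chance 10%). The next gene by p, Ly6a, had 128 ± 50.9 and 353 ± 85.5 CPM and did not pass (1.55 ± 0.32, 0.0826).

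**Figure D3:**
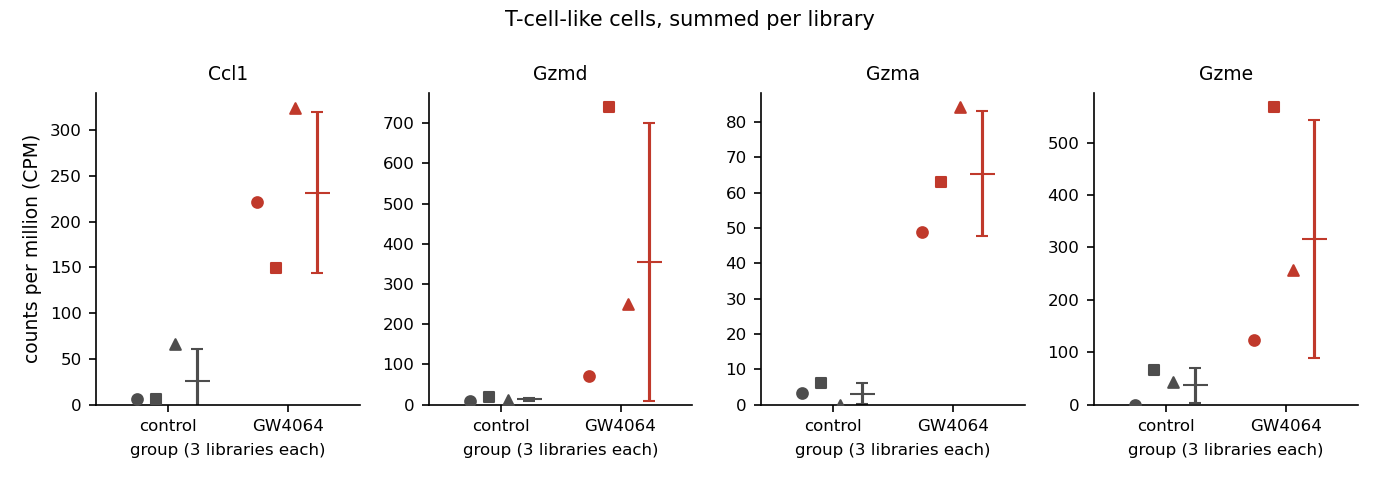
CPM of the 4 genes past the threshold in T-cell-like cells (y axis, CPM; x axis, group), 1 point per library with replicates 1, 2 and 3 as circle, square and triangle, and the mean with SD beside them. GW4064 replicate 2 has the highest Gzmd and Gzme values.

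Among the gene lists in T cells, hypoxia and glycolysis ranked first (14 members, median 0.60, adjusted p 0.00113, Aldoa at 0.81 and Tpi1 at 0.87), followed by cytotoxic effectors (13 members, median 0.47, 0.00115). With the estimated correlation neither passed (adjusted p 0.603 for both). In the cytotoxic list Gzma rose and 4 members passed when adjusted over the list alone: Gzma, Gzmb (1.47 ± 0.42), the death ligand Fasl (1.15 ± 0.41) and the chemokine Ccl5 (0.97 ± 0.36). Interferon-gamma regulators (0.00225, Gbp2 at 1.55 and Gbp7 at 0.81), MHC class I (0.00345, Psmb10 at 0.85 and Erap1 at 1.12) and cell cycle (0.0137, Tyms at 1.102 and Birc5 at 0.94) were shifted upward (estimated 0.370, 0.603 and 0.603). Mitochondrially encoded genes (0.00897, mt-Co1 at -0.51 and mt-Nd6 at -0.65) and immediate early genes (0.0137, Zfp36 at -1.11 and Klf2 at -1.07) were shifted downward (estimated 0.603 for both). Apart from the cytotoxic list, 0 members of these lists passed when adjusted over the list alone. Hypoxia, interferon-gamma, MHC class I and cell cycle lists were also shifted upward in tumour-like cells. RNA of tumour-like cells in T-cell-like barcodes was not measured, nor in monocyte/macrophage-like or fibroblast-like barcodes. For these lists it was therefore not told apart from transcripts of the class itself. The estimated correlation gave 0 of 18 lists and fry gave 0 (lowest 0.0743). Without control 1, 3 lists passed and the cytotoxic list did not (0.107). Without GW4064 2, 4 lists passed. Cell cycle passed in 7 of 10 settings (0.696 without control 3), immediate early genes in 6 (0.191 without control 1), mitochondrial genes in 7 (0.155 without GW4064 2) and MHC class I in 9 (0.168 without control 1).

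In fibroblasts single matrix genes were among those that changed. Col6a5, a collagen VI chain, rose from 1.52 ± 1.32 to 51.7 ± 14.5 CPM (SD, n = 3; log2 fold change 4.98 ± 0.48 SE, adjusted p 0.000427). Smpd3, a sphingomyelinase of matrix mineralization, rose from 6.23 ± 5.68 to 143 ± 101 CPM (4.40 ± 0.61, 0.00389), and the methyltransferase Inmt from 1.01 ± 1.75 to 22.0 ± 6.14 CPM (4.44 ± 0.65, 0.00694). Tnc, the wound and tumour matrix protein tenascin C, fell from 1976 ± 353 to 588 ± 27.8 CPM (-1.75 ± 0.22, 0.00234). Col23a1, a transmembrane collagen (-2.13 ± 0.39, 0.0318), and Cdkn2b, a cell-cycle inhibitor (-2.15 ± 0.35, 0.0145), fell as well. Of 8251 genes tested with edgeR, 32 passed (26 up, 6 down).

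Col6a5, Smpd3 and Tnc kept direction and call under all 15 alternatives, with adjusted p up to 0.00815, 0.0391 and 0.0362. Inmt lost its call without GW4064 2 (0.0636) and without control 3 (0.0752). Col23a1 lost it without GW4064 2, control 1 or control 3 (0.115, 0.151 and 0.202). Cdkn2b lost it without GW4064 2, control 1, 2 or 3 (0.0675, 0.0530, 0.0604 and 0.130). DESeq2 called 87 genes, all 32 among them. The count was 137 without GW4064 1, 14 without control 1 and 11 without control 3. No overlap was seen for 1358 genes (16.5%, chance 10%), and the sums rested on 49 to 158 cells per library.

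**Figure D4:**
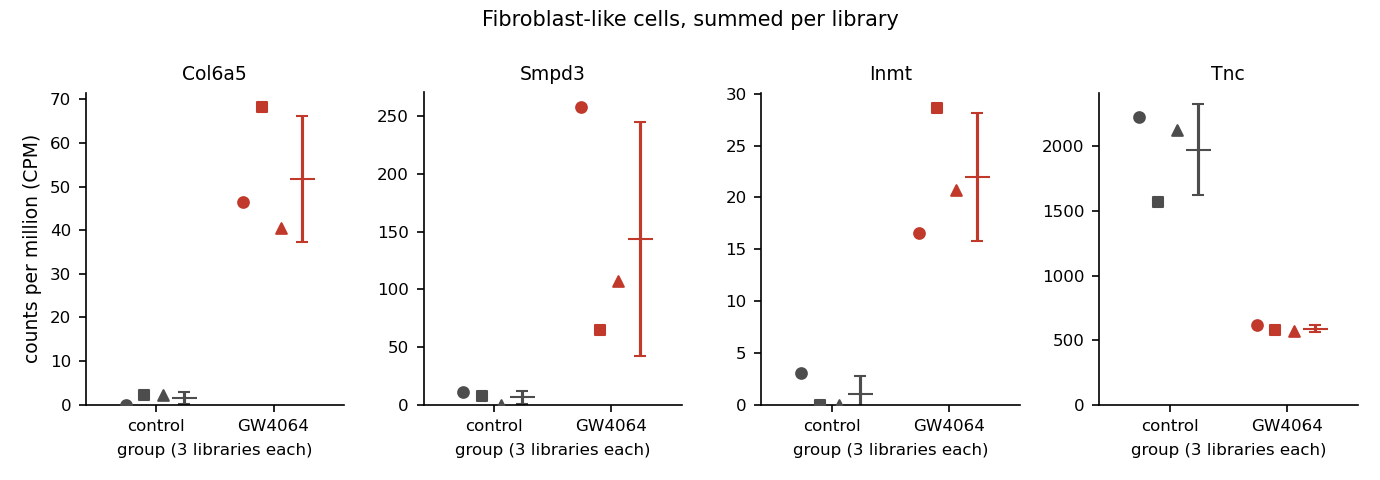
CPM of 4 genes in fibroblast-like cells (y axis, CPM; x axis, group), 1 point per library with replicates 1, 2 and 3 as circle, square and triangle, and the mean with SD beside them. Tnc lies between 567 and 619 CPM in GW4064 libraries and above 1572 CPM in all 3 control libraries.

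The lists of antigen presentation and interferon-gamma were shifted upward in fibroblasts too, while that of type I interferon did not pass (adjusted p 0.0542). MHC class I had a median log2 fold change of 1.06 over 16 members (adjusted p 7.41e-14, estimated correlation 0.432), led by H2-Q6 (1.68, 0.0501), Tap1 (1.51, 0.0540) and H2-K1 (1.32, 0.0560). None of them passed over all genes, and all 16 passed when adjusted over the list alone. In the interferon-gamma list (4.05e-13, estimated 0.432) the chemokine Cxcl9 (2.61 ± 0.41, 0.0115) and the interferon-induced GTPases Iigp1 (2.32 ± 0.38, 0.0145) and Gbp2 (2.46 ± 0.42, 0.0191) rose, and 11 of 12 passed when adjusted over the list alone. The Cxcl9 call was lost without control 3 (0.136), that of Iigp1 without GW4064 2, control 1 or control 3 (0.0655, 0.0966 and 0.188), and that of Gbp2 without GW4064 2, control 1, 2 or 3 (0.0740, 0.115, 0.0639 and 0.188). In the MHC class II list (3.76e-11, estimated 0.0920, fry 0.0166) H2-Aa (3.82 ± 0.38, 0.000427), Cd74 (3.35 ± 0.42, 0.00216) and H2-Eb1 (3.76 ± 0.58, 0.0103) rose, and all 5 members passed when adjusted over the list alone. These 3 stood at 0.005 to 0.006 of the level in the highest class, and immune RNA in fibroblast-like barcodes was not measured, so the values do not separate it from transcripts of fibroblasts. H2-Eb1 lost its call without GW4064 2, control 1 or control 3 (0.0655, 0.0641 and 0.0752), and Cd74 at Leiden resolution 0.5 (0.0680). The cell-cycle list (4.94e-05, estimated 0.489) had 1 of 24 members up, Mcm3 of the replication helicase (1.20 ± 0.24, 0.0494), also when adjusted over the list alone, with Mcm6 at 0.73. Mcm3 kept its call in 7 of 15 alternatives and lost it without GW4064 2 and without each control replicate, with adjusted p up to 0.264. Heat shock genes (0.0295, estimated 0.489, Dnajb1 at 0.67 and Hspa1a at 1.00) were shifted upward and extracellular matrix genes (0.00316, estimated 0.489, Col5a1 at -0.77 and Col6a1 at -0.54) downward, with 0 members past when adjusted over the list alone. Heat shock passed in 7 of 10 settings (0.248 without control 3) and extracellular matrix in 9 of 10 (0.0518 without GW4064 3). Without GW4064 1, 9 lists passed in place of 6.

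In tumour-like cells interferon and antigen-presentation lists were shifted upward with the preset correlation, but none passed with the estimated one (lowest adjusted p 0.464), and no single gene passed. The lowest adjusted p was 0.0977, shared by Anxa8, a membrane-binding annexin (32.0 ± 1.1 and 91.1 ± 18.5 CPM, SD, n = 3; log2 fold change 1.51 ± 0.16 SE), and Serpinb9b, a serpin of the granzyme-inhibitor family (1.52 ± 0.294 and 11.3 ± 5.02 CPM, 2.90 ± 0.32). The same value held for the growth-cone protein Basp1 (1.49 ± 0.19), the membrane protein Tmem184a (1.69 ± 0.21) and the synaptic pentraxin Nptx1 (-2.89 ± 0.37). Tumour-like cells of control libraries were most often in clusters 3, 4 and 6 (15.5, 15.9 and 13.2% of retained cells), while clusters 0 and 12 held 16.1 and 15.2% on average under GW4064. These averages come mostly from GW4064 2 and 3, as GW4064 1 had 6.48 and 3.71% there and more in clusters 3, 4 and 6. Of 14633 genes, edgeR called 0, with 2026 at unadjusted p under 0.05, and DESeq2 621 (389 up, 232 down).

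That count depends on single choices and libraries. The edgeR count was 499 without GW4064 1, 1 without GW4064 3 and 327 without the filter on low counts. Without GW4064 2 it called 0 (2245 at unadjusted p under 0.05). Over 17 alternatives the adjusted p of Anxa8 ran from 8.13e-14 to 0.471 and its log2 fold change from 1.34 to 1.63. The groups did not overlap in 3429 genes (23.4%, chance 10%).

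The interferon-gamma list in tumour-like cells had a median log2 fold change of 2.21 over 16 members (adjusted p 5.73e-11, estimated correlation 0.464), and 15 passed when adjusted over the list alone. Among its leading members were Irf8 (1.79 ± 0.33), Igtp (13.9 ± 7.38 and 83.0 ± 45.8 CPM, 2.58 ± 0.56) and Gbp3 (2.55 ± 0.56), with adjusted p 0.115 to 0.133 over all genes. MHC class I followed (median 1.08, 6.29e-10, estimated 0.464), with the peptide transporter Tap1 at 22.1 ± 7.07 and 78.2 ± 37.1 CPM (1.82 ± 0.40, 0.132), H2-Q6 (2.27), Nlrc5 (1.08) and Tapbp (1.08), and 17 of 17 passed when adjusted over the list alone. The type I interferon list (median 1.20, 1.52e-06, estimated 0.495) was led by Zbp1 (2.25), Oas1a (2.02) and Bst2 (1.60), with 11 of 19 past when adjusted over the list alone. MHC class II (median 2.72, 1.40e-05, estimated 0.464) was led by Ciita (2.84) and Cd74 (3.28), with 8 of 8. The estimated correlations between members were 0.81, 0.83, 0.77 and 0.86 for these 4 lists in this order, so their members are not separate results. In all 12 settings of the preset test these 4 lists passed. Irf8, H2-Q6, Ciita and Cd74 stood at 0.011, 0.006, 0.04 and 0.008 of the level in the highest class.

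**Figure D5:**
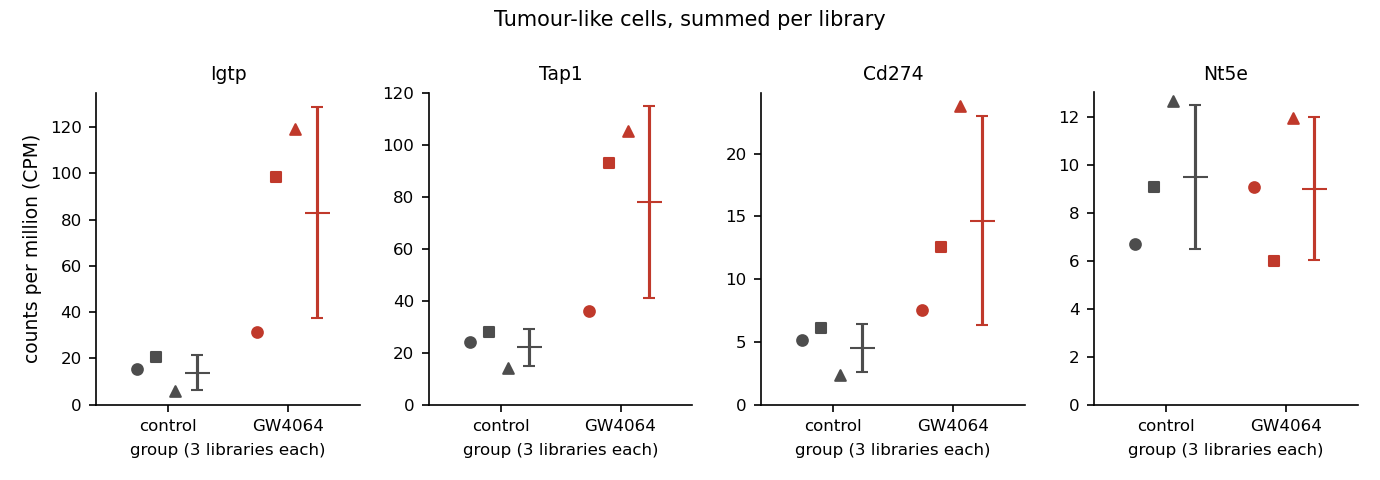
CPM of 4 genes in tumour-like cells (y axis, CPM; x axis, group), 1 point per library with replicates 1, 2 and 3 as circle, square and triangle, and the mean with SD beside them. Igtp, Tap1 and Cd274 lie higher in GW4064 libraries without passing the threshold, and Nt5e overlaps between groups.

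Further lists passed in tumour-like cells. Hypoxia and glycolysis (median 0.41, 1.70e-05, estimated 0.464) was led by the carbonic anhydrase Car9 (7.26 ± 1.78 and 15.1 ± 2.26 CPM, 1.06 ± 0.20, 0.115), Hk2 (0.56) and Pfkp (0.54), with 7 of 20 past when adjusted over the list alone. Extracellular matrix was shifted downward (median -0.22, 0.00917, estimated 0.464), with 4 members down and 1 up when adjusted over the list alone, led by Col6a1 (-0.81), Col4a1 (-0.77) and Fn1 (-1.30). Checkpoint genes (0.00123, estimated 0.464) had Havcr2 at 1.46, Lgals9 at 0.93 and Cd274 at 1.697, with 4 past when adjusted over the list alone. Cytotoxic effectors (median 1.21, 0.0107, estimated 0.495, Tnf at 1.32 and Ccl4 at 1.07), inflammatory cytokines (0.00917, estimated 0.464, Ptgs2 at 0.67 and Nos2 at 2.05) and cell cycle (0.00683, estimated 0.495, Rrm2 at 0.42 and Mcm5 at 0.38) had 0, 2 and 0. The unfolded protein response (0.0180, estimated 0.495, Chac1 at 1.31 and Sesn2 at 0.51) and MYC targets (0.0179, estimated 0.495, Rrp9 at 0.55 and Bop1 at 0.50) had 0. In all, 12 of 24 lists passed with the preset correlation, 0 with the estimated one and 0 with fry (lowest adjusted p 0.183). Without GW4064 2 the cytotoxic, stress-response and inflammatory lists did not pass (0.0987, 0.223 and 0.156), and without control 1 MYC targets did not (0.1003). Inflammatory cytokines and MYC targets each passed in 9 of 12 settings. Tnf, Ccl4, Nos2, Havcr2 and Col4a1 stood at 0.002, 0.001, 0.012, 0.031 and 0.009 of the level in the highest class. Macrophage RNA measured in tumour-like barcodes was 0.048% in control and 0.09% in GW4064 libraries. For Tnf and Ccl4, RNA of immune cells was therefore not told apart from transcripts of tumour-like cells.

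None of the genes of the study's question passed the threshold of the main test in the classes where they were tested. The filter on low counts left out Nt5e and Cd274 in fibroblasts, Fbxw7 in T cells, Pdcd1 in all classes but T cells, and Nr1h4 and Nr0b2 in every class and in whole tumours. Nt5e, which encodes the adenosine-producing enzyme CD73, was at 9.50 ± 3.01 and 9.01 ± 2.98 CPM in tumour-like cells (log2 fold change -0.08 ± 0.29 SE, adjusted p 0.906). In macrophages it was at 117 ± 5.35 and 71.2 ± 36.2 CPM (-0.72 ± 0.27, 0.516), and in T cells at 110 ± 39.3 and 86.7 ± 56.7 CPM (-0.32 ± 0.41, 0.888). Fbxw7, a ubiquitin ligase subunit, was at 32.7 ± 1.28 and 32.2 ± 5.36 CPM in tumour-like cells (-0.02 ± 0.14, 0.955), with -0.02 in macrophages and 0.22 in fibroblasts (0.996 and 0.842). RNA levels do not show protein degradation. The sign of Nt5e in tumour-like and T cells and of Fbxw7 in tumour-like cells and macrophages flipped under some alternatives, within -0.92 to 0.19. Without GW4064 1 Nt5e passed in macrophages (-1.21, adjusted p 0.00236), as it did without the filter on low counts. Cd274 (PD-L1) was at 4.53 ± 1.92 and 14.6 ± 8.32 CPM in tumour-like cells (1.697 ± 0.457, 0.172), at 0.04 of the level in dendritic-like cells, with 0.37 in macrophages (0.753) and -0.19 in T cells (0.932, from -0.65 to 0.05 over alternatives). In tumour-like cells it passed in 3 of 17 alternatives (DESeq2, no filter on low counts, and without GW4064 1), with adjusted p from 0.00385 to 0.518. Pdcd1 (PD-1) in T cells was at 86.4 ± 46.2 and 123 ± 22.2 CPM (0.62 ± 0.37, 0.759).

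The receptor that GW4064 activates was hardly detected. Nr1h4, which encodes it, had 32 UMIs over all cells, 25 of them in tumour-like cells, and its target Nr0b2 had 0 UMIs, which allows up to 3 counts among all retained UMIs. Of the farnesoid X receptor targets 5 were tested in tumour-like cells (adjusted p 0.327, estimated 0.495). The lipid transfer protein Pltp was at 11.4 ± 1.46 and 20.1 ± 4.15 CPM (0.82 ± 0.18, 0.132) and Osgin1 at 1.33 ± 0.133 and 2.25 ± 0.683 CPM (0.76 ± 0.25, 0.238), and both passed when adjusted over the list alone. Over all genes Pltp passed in 3 of 17 alternatives. The adenosine list (0.961) had 2 members up, Ada (0.72) among them, and 2 down, Enpp1 (-2.68) and Cd38 (-1.17), when adjusted over the list alone, and its median (0.05) and mean (-0.22) differed in sign. Enpp1 and Cd38 stood at 0.005 and 0.031 of the level in the highest class. In the 4 classes and whole tumours 0 of the 7 goblet cell genes reached the expression filter.

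Over whole tumours, where cell makeup and expression are mixed, the immune lists were shifted upward. Cytotoxic effectors had a median log2 fold change of 1.64 over 14 members (adjusted p 8.52e-07, estimated correlation 0.325), with Gzma (2.93 ± 0.66), Gzmb (2.55 ± 0.66) and the killer-granule protein Nkg7 (2.02 ± 0.53) in the lead, and 10 passed when adjusted over the list alone. Checkpoint genes (8.52e-07, estimated 0.325) were led by Pdcd1lg2 (2.73 ± 0.40, 0.0972) and Havcr2 (1.19 ± 0.22, 0.105), with 9 past when adjusted over the list alone. Interferon-gamma (1.22e-09, Irf8 at 1.46), MHC class I (2.42e-08, Tap1 at 1.71) and MHC class II (1.07e-05) had 15, 17 and 8, and with the estimated correlation an adjusted p of 0.325 each. Of 15796 genes edgeR called 0 (2551 at unadjusted p under 0.05, lowest adjusted p 0.0660) and DESeq2 737. The edgeR count was 453 without GW4064 1, and 1 gene without control 1 or without GW4064 2. No overlap was seen for 4243 genes (26.9%, chance 10%).

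Further lists in whole tumours that passed with the preset correlation were type I interferon (8.52e-07, estimated 0.382), cell cycle (1.13e-06), hypoxia (0.000105), MYC targets (0.00908), the unfolded protein response (0.0323), cholesterol synthesis (0.0323), oxidative phosphorylation (0.0339) and inflammatory cytokines (0.0481) upward. With the estimated correlation their adjusted p ran from 0.325 to 0.671 and none passed. Oxidative phosphorylation changed direction between settings and passed in 7 of 10 (0.978 without GW4064 2), and inflammatory cytokines passed in 5 of 10 (up to 0.120). Cholesterol synthesis passed in 7 of 10 (up to 0.171), the unfolded protein response in 8 (0.244) and MYC targets in 9 (0.0861). Extracellular matrix (0.000407, Col6a1 at -0.998 and Col4a1 at -0.86) and TGF-beta targets (0.00816) were shifted downward (estimated 0.325 for both). In all, 0 of 24 lists passed with the estimated correlation or with fry (lowest 0.0658), against 15 with the preset value. Adjusted over the list alone, 14 type I interferon genes, 5 cell-cycle, 2 hypoxia and 1 inflammatory gene were up and 8 matrix genes down. Cd274 was at 7.08 ± 1.99 and 19.6 ± 8.96 CPM (1.47 ± 0.34, 0.135, and 0.00104 to 0.376 over alternatives, with 3 of 13 past the threshold, among them that without GW4064 1), Pdcd1 at 0.169 ± 0.0743 and 0.553 ± 0.1997 CPM (1.72 ± 0.44, 0.152, and 0.0189 with DESeq2), Nt5e at -0.05 (0.933) and Fbxw7 at -0.02 (0.957). The direction of both last values flipped under some alternatives. Without control 1, 10 lists passed.

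Positions on GRCm38 are as follows. Nt5e (ENSMUSG00000032420) lies on chromosome 9 from 88327197 to 88372092 and Fbxw7 (ENSMUSG00000028086) on chromosome 3 from 84815268 to 84979198. Cd274 (ENSMUSG00000016496) spans 29367455 to 29388095 and Pdcd1lg2 (ENSMUSG00000016498) 29410919 to 29471161 on chromosome 19. Gzmd (ENSMUSG00000059256) spans 56129556 to 56132608 and Gzme (ENSMUSG00000022156) 56117626 to 56120625 on chromosome 14. Ly6a (ENSMUSG00000075602) spans 74994877 to 74998031 and Ly6i (ENSMUSG00000022586) 74979534 to 74983430 on chromosome 15. Tnc (ENSMUSG00000028364) lies on chromosome 4 from 63959785 to 64047015. All are protein-coding.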

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

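Both tests below were added after the results per class had been seen.

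Gsn and Slfn2 responded differently in tumour-like and fibroblast-like cells. Gsn encodes gelsolin, which severs actin filaments. Its log2 fold change was -0.27 in tumour-like cells and 2.26 in fibroblast-like cells, a difference of -2.59 (limma adjusted p 0.0111). Gsn was also a leading gene of the unnamed collagen-high cluster without Y-linked transcripts, which held 18.9% of control and 5.63% of GW4064 cells. That cluster is outside the tumour-like class, and the difference was not tested with it added. Slfn2, a Schlafen family gene of lymphocyte quiescence and interferon response, had 3.02 in tumour-like and 0.29 in fibroblast-like cells, a difference of 2.74 (adjusted p 0.0289). Of 8015 genes tested 2 passed, with 1161 at unadjusted p under 0.05.

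The other 5 pairs of classes gave 0 genes with limma, with a lowest adjusted p of 0.0528 for tumour-like against monocyte/macrophage-like cells (789 at unadjusted p under 0.05). Among the 10 splits of the libraries the real one gave 2 genes and the highest other 0, so only the real split itself reached 2. With 10 splits a share under 0.05 cannot be reached.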

How the results depend on the processing

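Of 148 gene and class pairs, 31 were called and all 31 kept their sign over the alternatives. Called genes had no overlap between groups, so leaving out a library could hardly turn their sign. Among 2271 alternative values 1957 had the same call and sign, 85 were weaker, 216 stronger and 13 changed sign without a call. Genes past the threshold, for tumour-like cells (0): DESeq2 621, no filter 327, leave-outs 0 to 499. For monocyte/macrophage-like cells (19): DESeq2 47, Leiden 0.5 58, 10% mitochondrial 29, no filter 253, replicate block 49, doublets kept 26, leave-outs 0 to 199. For T-cell-like cells (4): DESeq2 0, no filter 26, replicate block 9, leave-outs 2 to 17. For fibroblast-like cells (32): DESeq2 87, Leiden 0.5 50, Leiden 2 42, no filter 359, replicate block 52, doublets kept 48, leave-outs 11 to 137. For whole tumours (0): DESeq2 737, no filter 193, replicate block 9, doublets kept 1, leave-outs 0 to 453. Gene lists with the estimated correlation and with fry were 0 in tumour-like, monocyte/macrophage-like and T-cell-like cells (12, 10 and 7 with the preset), with leave-outs 6 to 10 in monocyte/macrophage-like and 3 to 8 in T-cell-like cells. Class shares (2): replicate block 0, immune cells only 0, with the collagen-high cluster 1, with all clusters without Y-linked transcripts 1, exact permutation 0, leave-outs 0 to 2. T subsets (0): at least 1000 genes 1, replicate block 1, of all retained cells 3. Of immune cells only, the log2 fold change of the monocyte/macrophage share was -0.10 (adjusted p 0.760), reversed from 0.89. Of all retained cells, regulatory T-like cells had 1.47 (adjusted p 0.0283), reversed from -0.02, since the denominator is no longer T and NK cells. The other causes were not tested. The shares of all retained cells, the clusters without Y-linked transcripts and the doublet rule were chosen after the data were seen. Same-number libraries correlated at -0.049, 0.084 and -0.020 in tumour-like cells, at -0.157 to -0.084 in monocyte/macrophage-like cells, -0.005 to 0.252 in T-cell-like cells and -0.037 to 0.109 in whole tumours. In none of these 4 did every library correlate best with its own number or were all 3 pairs above 0.1 (fibroblast-like cells were not checked), so the numbers were not taken to pair the libraries.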

Other observations

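All 3 tests on interferon genes, the test of transcript length, the tests of granzymes alone and of Ccl1 alone against the subset mix, and the splits for T-cell subset shares were chosen only after the result was seen.

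Interferon-gamma and MHC class I genes were higher in tumour-like cells under GW4064 as a set, with a median log2 fold change of 1.79 over 33 genes. No member passed over all genes, and with the estimated correlation neither list passed (adjusted p 0.464 for both). RNA from monocyte/macrophage-like or T-cell-like cells in the droplets does not account for it. The smaller ratio of needed to measured RNA was 492 (44.2% needed, 0.09% measured from macrophage transcripts). RNA of dendritic-like and NK-like cells in these droplets was not measured. GW4064 2 is not the whole cause either, as without it the median was 1.41. A candidate explanation is more interferon-gamma per tumour. Ifng over all cells had a log2 fold change of 1.62 (adjusted p 0.202) with 84.1% of its 775 UMIs in T-cell-like cells, so this stays undecided.

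GW4064 2 may carry a technical difference linked to transcript length. Its deviation correlated with length at a Spearman's rho of -0.71, against at most 0.267 in size in the other libraries. That reference was changed after the first result was seen: with GW4064 2 among the reference libraries another library reached 0.621, and the condition could not be met. For GC content rho was 0.296, with 0.139 in the others (0.3 in the first form), which stays undecided. Cell makeup does not explain it, since its deviations in tumour-like and macrophage-like cells went together (r 0.775, others at most 0.391).

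Granzymes and Ccl1 were higher in T-cell-like cells. NK markers among them moved by -8.62% of the NK level (median, with single markers from -19.6 to -0.651%), where granzymes would need 5.49%. Such markers were also present in control T-cell-like cells, as Klre1 at 96.3 CPM against 257 in NK-like cells. The test is therefore too coarse to decide on NK-like cells as a source of the granzymes. Ccl1 would need an NK share of 260%, so NK-like cells are an unlikely source of Ccl1. In CD8 T-like cells the median of the 4 genes was 3.87 against 3.91 in all T-cell-like cells, and that of the granzymes 4.41 against 4.08, but both medians rest on Gzma, with 1 UMI in the CD8 T-like control cells. Gzmd had 4.54 against 4.79 and Gzme 3.34 against 3.43. Ccl1 had a smaller rise, with 1.73 ± 0.51 SE in CD8 T-like cells against 3.74 in all T-cell-like cells. Its groups overlapped in CD8 T-like cells, at 22.5, 9.63 and 119 CPM in control and 8.26, 78.9 and 184 CPM in GW4064 libraries. With fixed levels in each of the 4 T-cell sub-classes, a changed mix gives at most the largest fold of a sub-class share of UMIs. This was 0.57 on the log2 scale between group means and 1.41 between the most distant libraries. The log2 fold changes less 2 SE were 2.65 for Ccl1, 3.31 for Gzmd, 2.77 for Gzma and 2.12 for Gzme. In the main fit a mix of these sub-classes is therefore not the source. A changed share of a finer group is not covered by this bound. At Leiden resolution 0.5, Gzmd, Gzme and Ccl1 were among the leading genes of a sub-cluster of 59 cells. The bound replaced a test for Ccl1 in which 1 of 2 sub-classes with enough UMIs was more than 4-fold higher. With DESeq2 and with at least 1000 genes per cell Ccl1 was less certain (3.37 ± 0.997 and 2.83 ± 0.941 SE). Less 2 SE, both values fell below the bound of 1.41, so under these settings a mix stays open for Ccl1. The granzymes were not set against the bound under the alternatives. With DESeq2 none of them passed (adjusted p 0.999 for Gzme), so a mix is not excluded for them there. The UMIs of Ccl1 in CD4 T-like cells were 0 in control and 219 in GW4064 libraries. They came from 0 of 25 and 13 of 76 cells, with 87 of them in 1 cell. A rise within sub-classes and a few strongly expressing cells were not told apart.

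A test in CD8 T-like cells alone was added, although with 24, 29 and 12 cells in the control libraries they fall short of the minimum of 30 cells per library set for other classes. With edgeR, here with the filter on low counts that the values above lack, 4 of 1714 genes passed, Gzmd (4.21 ± 0.63, adjusted p 0.00400) and Gzme (3.03 ± 0.53, 0.00953) among them, while Ifng (-0.39, 0.875) and Pdcd1 (0.31, 0.855) did not. Also added was the share of T-cell-like cells without the unnamed sub-cluster, at 0.531 ± 0.193% and 1.81 ± 0.418% (1.77 ± 0.33, edgeR adjusted p 0.00159).

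With 10 splits of the libraries a share under 0.05 cannot be reached. The real split is itself counted among the splits as large as the real one. For genes, the splits as large as the real one were 10 in tumour-like cells (real 0, highest other 0), 1 in monocyte/macrophage-like cells (19, 1), 3 in T-cell-like cells (4, 17), 1 in fibroblast-like cells (32, 1), 10 in whole tumours (0, 0), 1 in CD8 T-like cells (4, 2) and 1 for the difference in response between tumour-like and fibroblast-like cells (2, 0). In T-cell-like cells 2 other splits called 13 and 17 genes, several times the real 4, which points to a structure of the samples that was not tested further. Both of these splits set GW4064 1 beside control 1 and another control library. In control 1 and GW4064 1, CD8 T-like cells held 27.1 and 34.6% of T-cell-like UMIs, against 50.7 to 68.1% in the other libraries. An unnamed cluster led by immunoglobulin genes held 2.18 and 0.88% of retained cells there, against 0.052 to 0.21% elsewhere. Whether these differences gave the calls was not tested. For gene lists the splits as large as the real one were 1 in tumour-like cells (12, 11), 1 in monocyte/macrophage-like cells (10, 8), 2 in T-cell-like cells (7, 7), 5 in fibroblast-like cells (6, 9) and 1 in whole tumours (15, 11). For class shares it was 1 (2, 0) and for T-cell subset shares 10 (0, 2).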
